A study of Homo sapiens with 21 samples.

How the data were processed

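Amplified cDNA libraries were sequenced from MDA-MB-231 cells that carry a miR-125b promoter reporter and were sorted at the top 5% (high, 12 libraries) and bottom 5% (low, 9 libraries) of its signal. Per the labels, cDNA was made by whole-transcriptome amplification with a SMARTer Ultra Low kit, libraries with a NEBNext Ultra kit, and sequencing was on a HiSeq 2000. The authors' deposited count table holds raw read counts per Ensembl gene and library, not normalised, and the labels list TopHat, HTSeq, DESeq2 and the build hg19 without versions or settings. The authors' deposited table of 303 genes gives a mean of normalised counts, a log2 fold change and its standard error on the log2 scale. Its sign was low over high when tested against the counts. The same deposited table gives a test score (the Wald statistic, by its column name) and a p-value and adjusted p-value computed by the authors.

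The 21 count columns were assigned to a gate by the letter of their code, since the numbers in the codes are not the replicate numbers of the labels. All 21 columns were used. The table has 48162 genes, of which 45650 had a symbol in the reference gene names, and the 2512 others held 0.510% of all counts. Of all genes, 25530 had no count in any library. Coordinates are 1-based, from a GRCh37 annotation, which is the same build as hg19. The total of 11248513 to 21511861 counts per library is the depth behind each value, and with amplified reads that lack molecular identifiers it bounds counting error only. Strand specificity was not stated, so reads of overlapping antisense genes cannot be separated, and reads of the near-identical genes HBA1 and HBA2 may be exchanged.

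Counts were scaled to CPM by each library's total over the tested genes times its TMM factor, for tested and untested genes alike. The comparison of high with low used edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust quasi-likelihood F test), which kept 7635 genes, with Benjamini-Hochberg adjustment over all of them and a threshold of 0.05. Log2 differences are high over low. Gene lists, the comparisons, the rule for named genes and the other settings to try were fixed before the data were examined. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Among the list names, 1 S phase gene (UHRF1), 1 inflammatory gene (SOD2), 4 histone genes and 1 endothelial gene (PECAM1) had no match in the count table. The 5 genes with the smallest p in each direction are named where none passed, with the host transcripts of miR-125b, the 2 members of each list with the smallest p, and BAK1, HAX1, ETS1 and STARD13. Some other genes that this rule picks, and 1 of the lists, are not reported here, though counts over all genes and lists include them. Other named genes were chosen after their values were seen, among them the platelet genes and the genes picked from the authors' deposited table.

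Host transcripts and library measures were compared on log2(CPM + 1) and on the measure itself with exact 2-sided permutation tests over all 293930 splits. The interval for MIR100HG holds the shifts that this test did not reject, in steps of 0.01. For miR-125b sites, the longest annotated 3′ UTR of each tested gene was searched for CTCAGGG and TCAGGGA. The difference in log2 fold change between genes with and without a site was adjusted for UTR length and mean expression and set beside the same measure for 200 random 7mers of the same bases.

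The settings chosen at that stage were other normalizations, other count filters, DESeq2 1.42.0, limma-voom with sample weights, a fit that is not robust, the number of genes detected as a covariate, and, for genes but not for gene lists, leaving out each library in turn. Settings added after seeing the data were leaving out each library in turn for gene lists, the library class as a covariate, fits within each class, leaving out L9, L10 and L11 or any 3 low libraries, DESeq2 without replacement of outlier counts, and an exact rank-sum test for each gene. The same tests were run on divisions of the 21 libraries into 12 and 9, the real one and random others, 100 in all for edgeR and camera, 32 for DESeq2 and 24 for edgeR with no filter. The tests were also tested on simulated data with the spread of these libraries. There edgeR called 3 of 7410 unchanged genes and DESeq2 132, in the simulated comparison of high against low over 7635 genes. DESeq2 called 0 of the same 7635 genes in the real counts. The simulated counts therefore differ from the real ones, and the rates found there describe simulated counts only. A gene set of 25 genes changed 4-fold gave a camera p of 8.354e-06 there, and a random set of 25 genes gave 0.368. Genes were drawn independently there, while the estimated correlation of the real lists reached 0.71, for G2 and M phase genes. That check therefore cannot show how camera at the preset correlation behaves on correlated lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Mature miR-125b, the EGFP reporter and the number of cells behind each library were not used here.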

Results

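MDA-MB-231 is an established human triple-negative breast cancer cell line, that is, a line without oestrogen receptor, progesterone receptor and ERBB2 amplification. The cells here carried EGFP under a promoter of the microRNA miR-125b, and were sorted by flow cytometry at the top 5% and the bottom 5% of the reporter signal. The comparison addresses how the transcriptome differs between cells with high and low activity of that promoter. There were 12 libraries from the high gate and 9 from the low gate, with 11248513 to 21511861 counts per library. Between 5327 and 12769 genes had at least 1 count in a library. Libraries are named here by the letter and number that head their columns in the deposited table (H3 to H14 for high, L2 and L4 to L11 for low), which are not the replicate numbers of the labels. The labels speak of single-cell cDNA libraries but give neither the number of cells behind a library nor the cultures or sorts they came from. The p-values below therefore measure only the spread between these libraries, and if each library is 1 cell they compare cells, not independent cultures.

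The epithelial keratins KRT8 (median 476 CPM, that is, counts scaled to the TMM-adjusted library size) and KRT18 (median 448 CPM) and the mesenchymal filament gene VIM (median 127 CPM) had counts in all 21 libraries. The oestrogen receptor gene ESR1 did not exceed 0.134 CPM in any library, and the E-cadherin gene CDH1 did not exceed 0.141 CPM. The spread between libraries was wide: over the 7635 genes tested, the Pearson correlation of log2(CPM + 1) between 2 libraries ran from 0.31 to 0.62 over the 210 pairs, across genes within each pair. Its median was 0.44 for pairs within a gate and 0.45 for pairs across the gates, and genes are not independent replicates. The common biological coefficient of variation was 1.84. The most alike 2 libraries still differed at 7535 genes, so no library appeared more than once. In 6 libraries (4 high: H3 to H6; 2 low: L2 and L4) 10248 or more genes were detected, and in the other 15 (8 high, 7 low) at most 9669. No label names this division, and it is called the library class below.

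The first question was whether the transcripts that carry miR-125b followed the gate. MIR100HG is the long noncoding host transcript of miR-125b-1, on chromosome 11 from 121899033 to 122427429 of GRCh37 (minus strand). It had counts in 12 of 12 high and 9 of 9 low libraries. Its level was 84.9 ± 60.02 CPM (SD, n = 12) in high libraries and 78.4 ± 71.8 CPM (SD, n = 9) in low libraries. Within the high gate it ran from 14.2 to 165.3 CPM, and within the low gate from 0.182 to 215.6 CPM. The fitted log2 difference of high over low was 0.11 ± 0.79 (SE), with an edgeR adjusted p of 1.00. On log2(CPM + 1) the difference of means was 0.78 with a 95% interval of -0.87 to 2.49, and an exact 2-sided permutation test over all 293930 splits gave p = 0.365. Without L9, L10 and L11 the difference of means was 1.59 (exact permutation p = 0.0894), and limma-voom over all libraries gave 1.63 (adjusted p of 0.998). Within the library class with fewer genes the log2 difference was 0.81 (exact permutation p = 0.308), and within the other class it was 1.67 (exact permutation p = 0.467, where 15 splits allow no p under 0.0667). In that other class the means were 27.1 CPM in high and 28.1 CPM in low libraries. Its low libraries were L2 at 0.182 CPM and L4 at 56.1 CPM, the latter above every high library of the class, so the 1.67 came from L2. L2 was also among the libraries behind the 0.78, the 1.59 and the 1.63. Its limma-voom sample weight of 2.56 was the largest of all libraries. The lowest level in the class with fewer genes was 3.96 CPM, in the low library L8. The values 0.78, 1.59, 1.63 and 0.81 were not computed again without L2 or L8, so they are not separate evidence of a difference. MIR99AHG, the host of miR-125b-2 on chromosome 21 (17300616 to 18018683, plus strand), reached 51.0 CPM in the high library H5. It had counts in 1 of 12 high and 1 of 9 low libraries and was too low for the main test. The precursor genes MIR125B1 and MIR125B2 had no row in the count table, and mature microRNA was not analysed here, so these values describe host transcripts only.

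**Figure D1:**
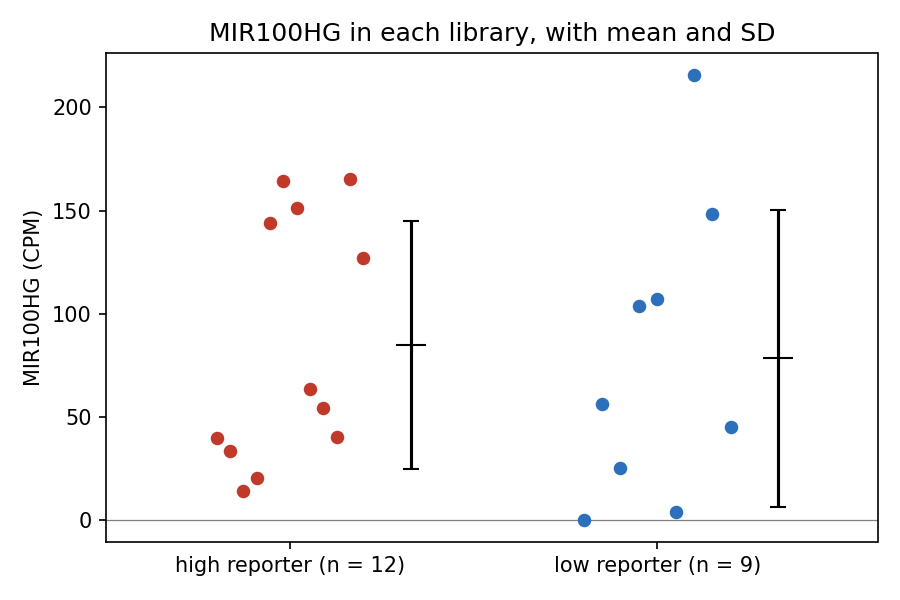
MIR100HG in CPM (counts scaled to the TMM-adjusted library size; vertical axis, linear) in each of the 12 high and 9 low libraries (points), with the mean and SD of each gate (black). The gates overlap, with means of 84.9 and 78.4 CPM.

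No gene passed an adjusted p of 0.05 in either direction in edgeR's quasi-likelihood test of 7635 genes, where 47 genes had an unadjusted p under 0.05. In a calibrated test chance alone would put a share of about 0.05 of the genes there, far more than 47, so this test ran conservative in these data. Random other divisions of the libraries gave a median of 48. An exact rank-sum test, added after seeing the data, put 285 genes (3.73%) under 0.05 and also called 0. Among genes with higher fitted levels in high libraries, the 5 with the smallest p were PHC2, CTNNB1, ARAP1, TMBIM6 and TYK2, and none of them passed (adjusted p of 1.00 each). PHC2, a Polycomb group gene on chromosome 1 (33789224 to 33896696), was at 321 ± 145 CPM (SD, n = 12) in high and 144 ± 68.2 CPM (SD, n = 9) in low libraries, a log2 difference of 1.16 ± 0.35 (SE). CTNNB1, which encodes beta-catenin, on chromosome 3 (41236232 to 41301587), was at 261 ± 96.7 CPM (SD, n = 12) and 108 ± 80.2 CPM (SD, n = 9), a log2 difference of 1.27 ± 0.42 (SE). ARAP1 had counts in 10 of 12 high and 2 of 9 low libraries, and TYK2, a Janus family kinase gene, in 9 of 12 and 2 of 9. TMBIM6 differed by 0.39 ± 0.14 (SE) on the log2 scale.

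Among genes with lower fitted levels in high libraries, the 5 with the smallest p were SH3BGRL3, HBA2, TMEM30A, HBB and SPTSSA, and none of them passed either (adjusted p of 1.00 each). SH3BGRL3, on chromosome 1 (26606577 to 26608013), was at 433 ± 196 CPM (SD, n = 12) in high and 945 ± 715 CPM (SD, n = 9) in low libraries, a log2 difference of -1.12 ± 0.33 (SE). TMEM30A, which encodes a subunit of phospholipid flippases, differed by -0.74 ± 0.26 (SE). SPTSSA, which encodes a small subunit of serine palmitoyltransferase, differed by -1.40 ± 0.53 (SE). The haemoglobin genes HBA2 (-5.04 ± 1.63, SE) and HBB (-4.67 ± 1.70, SE) rested on the low libraries L9, L10 and L11. Without those libraries, a choice made after seeing the data, HBA2 was at 0.60, HBB at -0.61, SH3BGRL3 at -0.54, TMEM30A at -0.48 and SPTSSA at -0.81. In simulated counts with a spread fitted to these libraries, the same test of high against low over 7635 genes found 3 of 50 genes changed 4-fold. It found 14 of 50 changed 16-fold and 33 of 50 changed 64-fold, so 4-fold and 16-fold differences were mostly missed in those counts. The limits in the real counts may differ, since DESeq2 called 132 of 7410 unchanged simulated genes but 0 of the 7635 real ones.

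Of 24 gene lists fixed before the data were examined, 22 had at least 3 tested members and entered camera. Cholesterol synthesis genes, nuclear oxidative phosphorylation genes and mitochondrially encoded genes were lower in high libraries with the preset correlation of 0.01. Cholesterol synthesis genes had a mean log2 difference of -0.50, with 16 of 21 tested members below 0 and an adjusted p of 0.00203. FDFT1, which encodes squalene synthase, was at 298 ± 194 CPM (SD, n = 12) and 622 ± 456 CPM (SD, n = 9), a log2 difference of -1.06 ± 0.45 (SE). MVK, which encodes mevalonate kinase, was at 2.70 ± 1.73 (SE) on the log2 scale, from counts in 6 of 12 and 6 of 9 libraries. Its medians were 0.0652 CPM in high and 0.392 CPM in low libraries, and its log2 difference was 0.16 in DESeq2 and -1.18 in limma-voom, so neither its size nor its sign held. Nuclear oxidative phosphorylation genes had a mean log2 difference of -0.22 (22 of 28 below 0, adjusted p of 0.0122), with UQCRQ at -0.57 ± 0.29 (SE) and COX4I1 at -0.44 ± 0.25 (SE). Mitochondrially encoded genes had a mean log2 difference of -0.63 (13 of 13 below 0, adjusted p of 0.0122), with MT-ND3 at -1.38 ± 0.68 (SE) and MT-ND2 at -0.53 ± 0.33 (SE). With an estimated correlation the adjusted p was 0.905 for each of the 3 lists, and fry gave an adjusted p of 0.909 for each. No member of these lists passed the threshold over all genes or adjusted over the list alone. Without L9, L10 and L11, which held haemoglobin and platelet transcripts, the adjusted p was 0.217 for cholesterol synthesis, 0.282 for oxidative phosphorylation, whose mean log2 difference then was -0.17, and 0.784 for mitochondrially encoded genes, whose camera direction then was up, with a median of 0.07 and a mean of -0.30. Of all 84 ways to leave out 3 low libraries, this one included, 23 ended the call for cholesterol synthesis, 38 for oxidative phosphorylation and 37 for mitochondrially encoded genes. Leaving out 1 library, or another test, also ended calls: oxidative phosphorylation was at an adjusted p of 0.0701 without H3, 0.148 without H4, 0.195 without H5 and 0.257 without L11, and mitochondrially encoded genes were at 0.756 with limma-voom, 0.0828 without H13, 0.0884 without L9 and 0.390 without L11. Summed cholesterol synthesis transcripts also followed the library class, at 757 to 1447 CPM in the 6 libraries with more genes and 2457 to 8786 CPM in the other 15. With the class as a covariate the adjusted p was 0.0194 for cholesterol synthesis, 0.0904 for oxidative phosphorylation and 0.0194 for mitochondrially encoded genes. In that fit with an estimated correlation it was 0.955 for each of the 3 lists. The oxidative phosphorylation mean was -0.22 with and without that covariate (SD over its members 0.22 in both fits), while the mean of the other genes moved from 0.08 to -0.03.

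Cell cycle genes had the largest medians of the 22 lists entered in camera, in opposite directions, and neither list passed. Of 12 tested G2 and M phase genes, 10 were above 0, with a median log2 difference of 1.21 and an adjusted p of 0.0674. CCNB1, which encodes cyclin B1, was at 677 ± 1826 CPM (SD, n = 12) in high and 29.4 ± 31.3 CPM (SD, n = 9) in low libraries, a log2 difference of 4.53 ± 1.91 (SE). The high library H11 alone held 6429.9 CPM of CCNB1, the medians were 38.6 CPM in high and 30.4 CPM in low libraries, and DESeq2 put the log2 difference at 2.34. CKS2 was at 1.29 ± 0.77 (SE) on the log2 scale. Of 19 tested S phase genes 18 were below 0, with a median log2 difference of -0.91 and an adjusted p of 0.0664. Summed S phase transcripts stood apart in 3 low libraries, L2 (11671 CPM), L7 (14278 CPM) and L8 (8952 CPM), against at most 6042 CPM in a high library. Sums over 2000 CPM were found in 6 of 12 high and 4 of 9 low libraries. PCNA, the sliding clamp of DNA replication, was at -1.63 ± 1.16 (SE), and SLBP, which binds histone mRNA, at -0.68 ± 0.40 (SE). Without L9, L10 and L11 the S phase list reached an adjusted p of 3.524e-05 at the preset correlation, with 27 members tested, and the G2 and M phase list was at 0.793 with 28. The S phase list also passed with the number of genes detected as a covariate (adjusted p of 0.0364) and with the library class (0.0194), and not with limma-voom (0.725). With the estimated correlation, which was 0.56 for S phase and 0.71 for G2 and M phase genes, the adjusted p was 0.905 for both lists over all 21 libraries.

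The other lists did not pass at the preset correlation in the edgeR fit, and none of their members passed over all genes; adjusted over the list alone, only HBA2 and HBB in the leukocyte and erythroid list passed. Unfolded protein response genes came closest, with 13 of 18 above 0 (adjusted p of 0.0671), and passed with limma-voom (0.0471) but not in the edgeR fit with an estimated correlation (adjusted p of 0.905). HSP90B1, an endoplasmic reticulum chaperone gene, was at 0.71 ± 0.28 (SE) on the log2 scale and PPP1R15A at 1.17 ± 0.48 (SE). Of glycolysis and hypoxia genes, 18 of 23 were above 0 (adjusted p of 0.193), with BNIP3L at 0.68 ± 0.39 (SE) and ALDOA at 0.36 ± 0.21 (SE). Mesenchymal genes had 12 of 17 above 0 (adjusted p of 0.766), with CALD1 at -1.40 ± 1.06 (SE) and THBS1 at 1.75 ± 1.44 (SE). THBS1 reached 1681 CPM in the high library H5 and was at 0.18 with limma-voom. Its medians went the other way, at 22.3 CPM in high and 57.6 CPM in low libraries. Epithelial genes had 5 of 12 above 0 (adjusted p of 0.496, and 0.0300 upward with limma-voom). In the edgeR fit with an estimated correlation the adjusted p of this list was 0.905. The claudin gene CLDN4 was at 0.53 ± 0.25 (SE) and JUP at -1.66 ± 1.62 (SE). The sign of JUP did not hold, at 1.51 with limma-voom and with medians of 12.0 CPM in high and 2.76 CPM in low libraries. Invasion and matrix protease genes had 12 of 16 above 0 (adjusted p of 0.766), with CTSB at 0.30 ± 0.24 (SE). Ribosomal protein genes lay near 0, with 16 of 37 above it (adjusted p of 0.766), and RPL7 was at -0.24 ± 0.21 (SE).

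None of the lists of death, damage and stress genes passed. BCL2 family and caspase genes had 13 of 21 above 0 (adjusted p of 0.786), with PMAIP1 at -0.43 ± 0.37 (SE) and CFLAR at 1.601 ± 1.53 (SE). DNA repair genes had 7 of 17 above 0 (adjusted p of 0.766), with ATM at 1.58 ± 1.68 (SE) and RAD50 at -0.95 ± 1.06 (SE). Immediate early and heat shock genes had 11 of 17 above 0 (adjusted p of 0.786), with DUSP1 at -1.66 ± 1.36 (SE) and JUND at -0.73 ± 0.85 (SE). In the NF-kB and inflammatory list (7 of 12 above 0, adjusted p of 0.847) the chemokine gene CXCL8 was at 9.36 ± 15.99 CPM (SD, n = 12) and 193 ± 485 CPM (SD, n = 9), with 1477 CPM in the low library L5 alone, and RELB was at 1.79 ± 1.83 (SE). The interferon list (3 of 8 above 0, adjusted p of 0.766) had ISG20 at -0.86 ± 1.54 (SE) and RIGI at -0.97 ± 1.79 (SE).

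Other short lists did not pass either. Stem cell markers had 6 of 8 above 0 (adjusted p of 0.855), with KLF4 at 1.74 ± 1.86 (SE) and EZH2 at -1.09 ± 1.66 (SE). Drug efflux transporters had 2 of 4 above 0 (adjusted p of 0.766), with ABCC3 at 1.17 ± 1.34 (SE) and ABCA2 at 0.86 ± 1.65 (SE). Replication-dependent histone genes had 2 of 5 above 0 (adjusted p of 0.766), with H4C3 at 1.09 ± 1.40 (SE) and H4C8 at -1.27 ± 1.81 (SE), and reads of these similar paralogs can be shared. The sign of H4C3 did not hold, at -0.68 with limma-voom, -0.28 with genes detected as a covariate and -0.30 with the library class. H4C3 medians were 7.38 CPM in high and 17.3 CPM in low libraries. MicroRNA pathway genes had 6 of 10 above 0 (adjusted p of 0.786), with XRN1 at 1.83 ± 1.86 (SE) and CNOT1 at 1.37 ± 1.43 (SE). The camera direction was opposite in sign to the list median for reported miR-125b targets, epithelial, immediate early and heat shock, and microRNA pathway genes, and opposite to the list mean for NF-kB and inflammatory genes.

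The next question was whether genes that miR-125b is reported to repress were lower where the reporter was high. Of 40 reported targets 18 were tested, 12 of them above 0, with a median log2 difference of 0.14 and an adjusted p of 0.766 in camera. The members with the smallest p were SGPL1 at 2.17 ± 1.20 (SE) and STAT3 at 0.68 ± 1.00 (SE). BAK1, a pro-apoptotic BCL2 family gene, was at 60.5 ± 87.2 CPM (SD, n = 12) in high and 41.3 ± 58.4 CPM (SD, n = 9) in low libraries. The anti-apoptotic gene HAX1 was at 0.25 ± 0.42 (SE) and the transcription factor gene ETS1 at 0.62 ± 1.64 (SE) on the log2 scale, with an adjusted p of 1.00 for each and for BAK1. The sign of ETS1 did not hold, at -0.47 with limma-voom, -2.51 with genes detected as a covariate and -2.44 with the library class. ETS1 medians were 4.80 CPM in high and 34.4 CPM in low libraries. BAK1 was at 0.55 in the main fit and above 0 with either covariate, but at -1.01 with limma-voom. HAX1 stayed above 0 in these settings. STARD13 had counts in 4 of 12 high and 4 of 9 low libraries and was too low for the main test. Of 7256 tested genes with an annotated 3′ UTR, 1669 held a match to the miR-125b seed (CTCAGGG or TCAGGGA). Adjusted for UTR length and mean expression, their log2 differences were higher by 0.07 than those of genes without a site. Of 200 random 7mers with the same bases, 162 gave a lower value and 49 a value at least as far from 0 (p = 0.249). The camera test of the set gave p = 0.234, and p = 0.687 with an estimated correlation.

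Markers of other cell types separated 3 low libraries from the rest. In L9, L10 and L11, 15 platelet genes summed to 3438 to 9144 CPM, against at most 687 CPM in a high library and at most 398 CPM in the other 6 low libraries. They are a platelet list of 20 genes without THBS1, SPARC, MYL9, GNG11 and ITGB3. Those were taken out by name, with no level cut-off, as genes that the line expresses. With all 20 genes the sums were 4235, 4668 and 10599 CPM in L9, L10 and L11. The next highest was H5 at 1799 CPM. PPBP, a platelet chemokine gene, was at 2077, 1594 and 4316 CPM in L9, L10 and L11, and PF4, which encodes platelet factor 4, at 573, 846 and 2111 CPM. The haemoglobin genes HBA1, HBA2 and HBB summed to 769, 1220 and 2395 CPM in the same libraries. All other 12 libraries of the class with fewer genes also held transcripts of the 15 genes, at 126 to 687 CPM. The 6 libraries with more genes held at most 9.07 CPM of them. With all 20 genes the classes overlapped, at 976 CPM in H4 and 1799 CPM in H5 against 233 CPM in L7. The platelet list was written after platelet transcripts had been seen in these libraries, so no call rests on it. Leukocyte markers were mixed. PTPRC reached 0.0911 CPM, MS4A1 reached 0.0909 CPM, and CD3E and LYZ had no count in any library, while NKG7 reached 19.6 CPM in L8 and ITGAX 16.2 CPM in H12. S100A8, a myeloid gene outside the list that was looked at after the data were seen, was at 82.7, 36.4 and 204.9 CPM in L9, L10 and L11 and at most 13.1 CPM in any other library. Over the 18 leukocyte and erythroid markers, 6 exceeded 10 CPM in some library, and over the 14 fibroblast and endothelial markers 6 did. None of the fibroblast and endothelial markers was high enough in enough libraries for the main test. The highest level of that list was 220.1 CPM, for CLDN5 in L11, and LUM reached 91.3 CPM in H8.

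**Figure D2:**
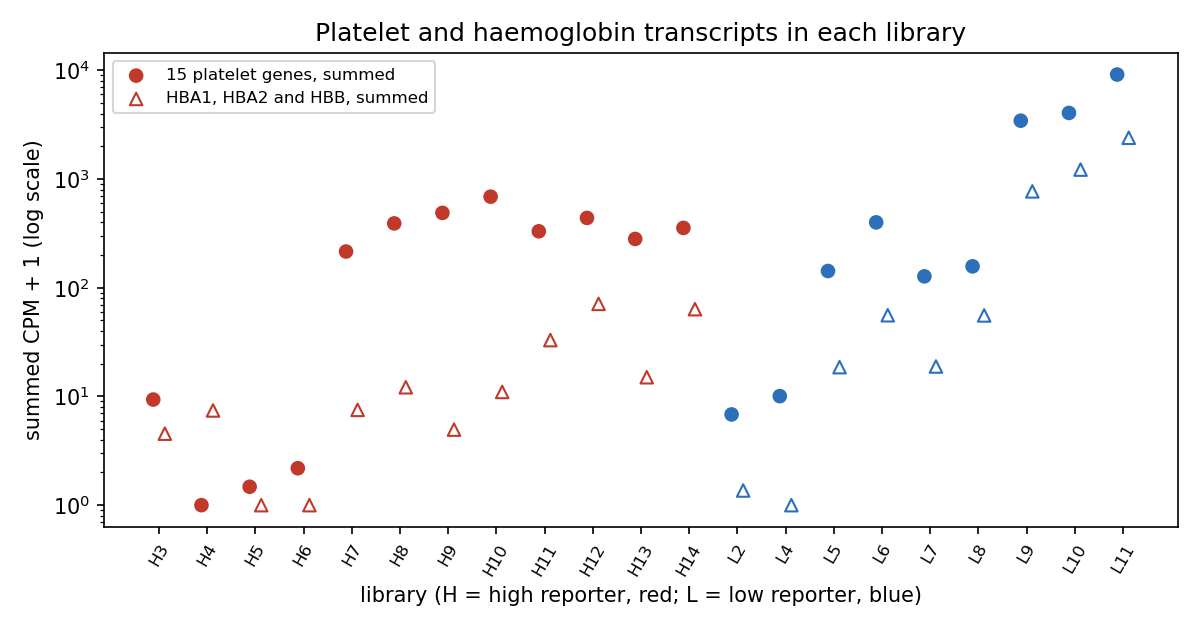
Summed CPM + 1 (vertical axis, log scale) of 15 platelet genes (filled circles) and of the haemoglobin genes HBA1, HBA2 and HBB (open triangles) in each library, with high libraries in red and low libraries in blue. L9, L10 and L11 lie above all others, at 3438 to 9144 CPM of platelet transcripts, and H3 to H6, L2 and L4 lie lowest, at up to 9.07 CPM.

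Library measures did not separate the gates. High libraries had 8688 ± 2391 genes detected (SD, n = 12) and low libraries 8707 ± 2096 (SD, n = 9; exact permutation p = 0.986, adjusted p = 0.986). Mitochondrially encoded genes took 3.24 ± 0.982% of counts (SD, n = 12) in high and 4.08 ± 1.497% (SD, n = 9) in low libraries (exact permutation p = 0.137, adjusted p = 0.821 over 6 measures). The smallest adjusted p over log10 total counts, genes with at least 1 and at least 10 counts, and the shares of mitochondrially encoded, ribosomal protein and 50 most abundant genes was 0.821 in the same exact permutation tests.

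The authors' deposited table lists 303 genes, 142 higher in low and 161 higher in high libraries. For 16 of the 303 the direction in the authors' deposited table was opposite to the difference of mean CPM, and DESeq2 here replaced at least 1 outlier count in 188 of them. By adjusted p its leading genes, named here after their values were seen, were KRBOX5 (log2 low over high of -26.27), LINC02492 (-24.99) and TRIM69 (-26.91) in the authors' deposited table. In the counts, KRBOX5 was found in 7 of 12 high and 0 of 9 low libraries, LINC02492 in 6 and 0, and TRIM69 in 6 and 0. ITGA2B, a platelet integrin gene, had a log2 value of 10.98 low over high in the authors' deposited table and counts in 2 high and 6 low libraries. Its level was 101, 47.9 and 222 CPM in L9, L10 and L11 and at most 3.29 CPM elsewhere, and it had no adjusted p in DESeq2 without those libraries. DESeq2 with its default settings on all genes with a count also called 303 genes, each of them in the authors' deposited table with the same direction. Of the 303, 193 had counts in at most 5 of the 21 libraries, and 186 had an absolute log2 value over 20 in the authors' deposited table. edgeR tested 3 of the 303 (ARAP1, HBA2 and SPTSSA), and none passed. With no filter beyond 1 count edgeR called 1326 genes higher and 1176 lower in high libraries, and DESeq2 on the 7635 genes that edgeR tested called 0, where 89 had an unadjusted p under 0.05. The closing part sets these counts beside those from other divisions of the same libraries.

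**Figure D3:**
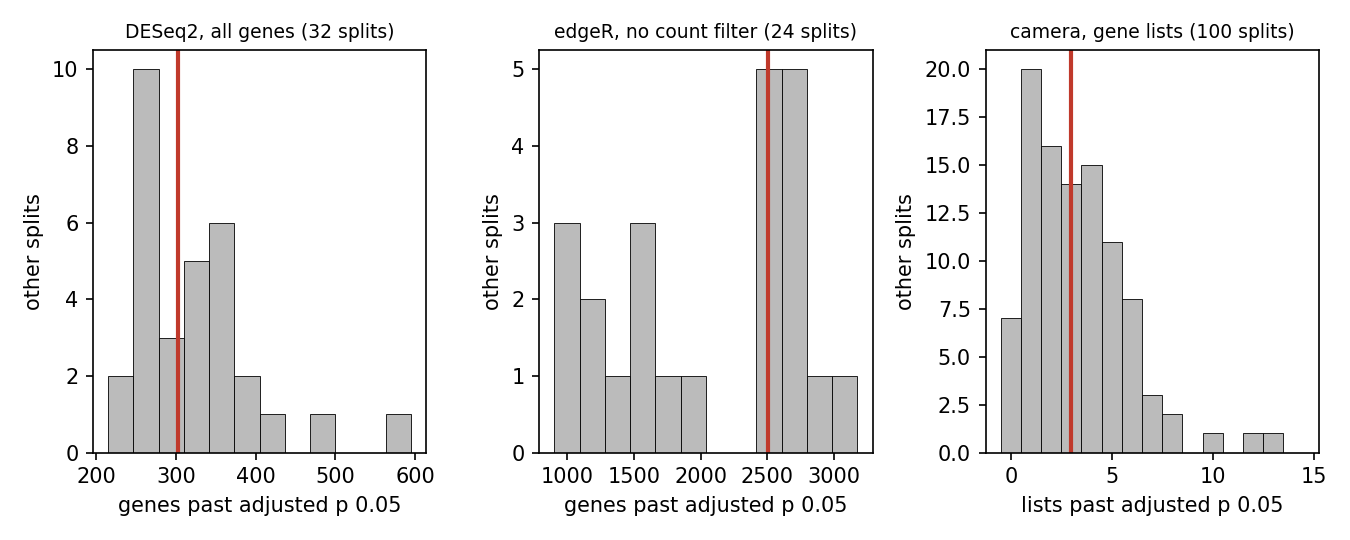
Number of other splits of the 21 libraries into 12 and 9 (vertical axes) by the number of genes past an adjusted p of 0.05 in DESeq2 on all genes (left) and in edgeR with no count filter (middle), and by the number of gene lists past it in camera (right). The red line is the real split, at 303 genes, 2502 genes and 3 lists, which lies inside the range of the other splits in each panel.

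**Figure D4:**
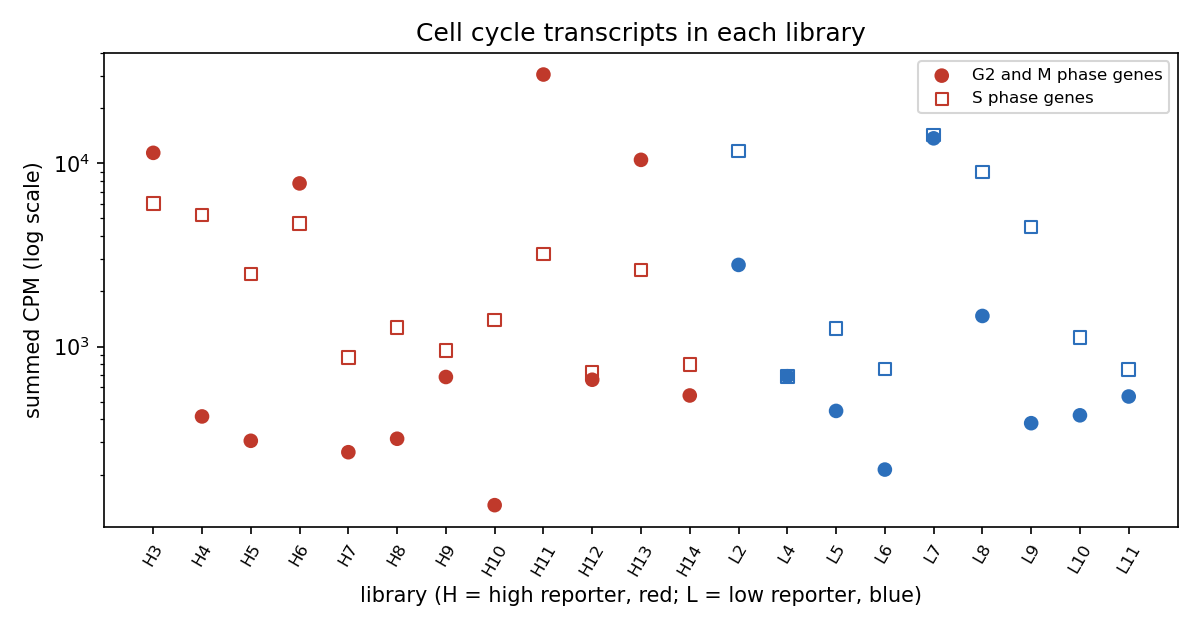
Summed CPM (vertical axis, log scale) of the G2 and M phase genes (filled circles) and S phase genes (open squares) in each library, with high libraries in red and low libraries in blue. G2 and M phase sums were 2790 to 30553 CPM in H3, H6, H11, H13, L2 and L7 and at most 1468 CPM in the other 15 libraries. S phase sums were highest in L7, L2 and L8, at 14278, 11671 and 8952 CPM.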

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

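The tests of replaced counts, of genes counted in few libraries, of blood cell RNA, read spill, the low gate, the library class and leaving out 3 low libraries were chosen only after the result was seen.

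Platelet and haemoglobin transcripts were high in the low libraries L9, L10 and L11, at 3438 to 9144 CPM for 15 platelet genes. Over 22 platelet and haemoglobin genes the lowest pairwise Pearson r among these libraries was 0.815, across genes, and their mean profile had r = 0.746 with that of the other 12 libraries with fewer genes. These genes and libraries were picked for such levels, so the r decides nothing and RNA of blood cells stays open. Leukocyte markers were mixed: PTPRC was at 0 in all 3 libraries and S100A8 at 36.4 to 204.9 CPM. Spill of reads from the other 18 libraries is argued against, since their highest PPBP level was 456 CPM and the lowest in L9 to L11 was 1594 CPM. All 3 libraries are low ones, and over all 12 high and 9 low libraries the platelet sum had an exact permutation p of 0.232, so a part of the low gate in it stays open, as does whether the cells or the preparation brought these transcripts.

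DESeq2 called 303 genes between the gates. Of 32 divisions of the libraries 17 gave at least as many (real 303, highest other 595), so chance cannot be excluded. edgeR with no filter called 2502 genes, and 13 of 24 divisions gave at least as many (highest other 3175), so chance cannot be excluded there either. Of the 303 genes, 193 had counts in at most 5 of the 21 libraries, and 105 stayed called when no outlier count was replaced. Of the others 29 were tested and not called, and 169 had no adjusted p in that setting. Both values are consistent with sparse counts and their replacement having shaped the list, mostly through which genes received an adjusted p, and a difference between the gates in some of these genes stays open.

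The third pattern was that 3 lists were lower in high libraries at the preset correlation. Of 100 divisions of the libraries 57 gave at least 3 lists (highest other 13), so chance cannot be excluded. For the number of genes at an unadjusted p under 0.05, 54 of 100 divisions gave at least the real 47 (highest other 200). For cholesterol synthesis, 18 of the 99 other divisions gave a camera p at least as small as the real 9.225e-05. With the library class as a covariate, 2 of the 3 lists, cholesterol synthesis and mitochondrially encoded genes, stayed past the threshold at the preset correlation. With an estimated correlation each of the 3 was at an adjusted p of 0.955 in camera. Random divisions often passed at the preset correlation, so passing there cannot decide whether the class was the whole cause. The mean log2 difference was -0.43 with the covariate against -0.50 for cholesterol synthesis, -0.87 against -0.63 for mitochondrially encoded genes, and -0.22 in both fits for oxidative phosphorylation. The call for the last of these ended (adjusted p = 0.0904) with no loss of fold, while the mean of the other genes moved from 0.08 to -0.03. Leaving out L9, L10 and L11 moved the cholesterol synthesis mean from -0.50 to -0.28. Of the 84 ways to leave out 3 low libraries, 17 gave a mean and 38 a median at least as high for this list. So for cholesterol synthesis the effect of L9, L10 and L11 cannot be told apart from that of leaving out other ones. For mitochondrially encoded genes 11 of the 84 raised the mean as much and 1, these libraries, raised the median to 0.07, so blood transcripts stay open there. For oxidative phosphorylation the mean moved from -0.22 to -0.17, and 33 of the 84 raised it as much, so these libraries did not stand out for it.

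Of 62 measures, 10 had 1 low library far from the other 8, with a gap over the range above 0.493. Chance gives about 1 in 20 for normally distributed values. That rate need not hold for sparse genes such as ARAP1 and TYK2, with counts in 2 of 9 low libraries each. So 10 of 62 cannot be read as an excess. On log2(CPM + 1), the highest values were those of MIR99AHG in L4 (gap share 1.00, which any single count gives, since L4 was at 0.0848 CPM and the other 8 at 0), ARAP1 in L2 (0.622), TYK2 in L5 (0.910), SH3BGRL3 in L11 (0.578) and COX4I1 in L11 (0.497). The lowest values were those of STAT3 (0.585), PMAIP1 (0.583), BNIP3L (0.646) and HAX1 (0.608) in L9 and that of CDKN1A in L4 (0.645). The 12 high libraries were too many for this rule and were not examined with it.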

How the results depend on the processing

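Results for gene lists with 1 library left out, results without L9, L10 and L11, with or within the library class, from DESeq2 without replacement or on the genes edgeR tested, and from the rank-sum test come from tests chosen only after the result was seen. No paired analysis was possible on the replicate numbers of the labels because no count column carries one, so that fit was not run. The codes H4 to H11 and L4 to L11 share numbers across the gates. Whether those numbers mark pairs is not stated, and a fit with the code number as a block was not run. edgeR called 0 genes with RLE, upper quartile, a stricter filter, a fit that is not robust, the detection covariate (127 at an unadjusted p under 0.05), each library left out, the class covariate, within each class and without L9, L10 and L11. With no filter it called 1326 genes higher and 1176 lower in high, and limma-voom called 0 higher and 1 lower (275 at an unadjusted p under 0.05). DESeq2 called 161 higher and 142 lower, 131 and 80 without L9, L10 and L11, 50 and 55 without replacement of outlier counts, and 362 and 662 with the class covariate; the cause was not tested for the last of these. An exact rank-sum test called 0 of 7635 genes, with 285 at an unadjusted p under 0.05. Camera called 3 lists, the same number with RLE, 4 with the detection covariate (S phase gained), 4 with limma-voom (epithelial and unfolded protein response gained, mitochondrially encoded lost), 0 with an estimated correlation, 1 without L9, L10 and L11, 5 within the 15 libraries with fewer genes, and 2 to 6 when 1 library was left out. Within those 15 libraries the adjusted p was 0.0361 for cholesterol synthesis and 0.00463 for mitochondrially encoded genes. Within the 6 libraries with more genes camera called 3 lists, with oxidative phosphorylation lower at 8.384e-05 and cholesterol synthesis not past the threshold (0.327). Directions reversed, past no threshold, for oxidative phosphorylation within the 15 libraries (adjusted p 0.986), and for mitochondrially encoded genes without L9, L10 and L11 (0.784) and within the 6 libraries with more genes (0.916); the cause was not tested. Over the libraries left out in turn, the adjusted p ran from 1.986e-05 to 0.0439 for cholesterol synthesis, 4.763e-04 to 0.390 for mitochondrially encoded genes and 0.00113 to 0.257 for oxidative phosphorylation. Of 59 tested genes that the rule for named genes picked, 0 passed in edgeR and 3 in DESeq2, and the direction held for 59 with DESeq2 and RLE, 57 with either covariate, 54 without L9, L10 and L11 and 52 with limma-voom. The MIR100HG log2 difference was 0.09 with RLE, 0.14 with no filter and 0.83 without L9, L10 and L11 in edgeR, and 1.63 with limma-voom, and passed in none of these. The site coefficient stayed between 0.07 and 0.12.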

Other observations

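The comparison of site coefficients with control 7mers that lack CG was chosen only after the result was seen. Among 100 divisions of the libraries, only the real one gave a site coefficient of at least 0.0721 in size (1 of 100 divisions, highest other 0.0671). That is the smallest share that 100 divisions allow. Several other patterns were also set against divisions, so chance is not excluded by this one. The sign was positive, that is, genes with a miR-125b site were slightly higher in high libraries, opposite to repression. Against 200 7mers of the same bases p was 0.249, and against the 55 without CG it was 0.0536, so the coefficient was not set apart from those of other sequences.

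Library class and cell cycle values were also seen. INSIG1, a sterol-regulated gene, was at 21.3 to 191 CPM in the 6 libraries with more genes and at 385 to 2265 CPM in the other 15. The classes overlapped for MSMO1 (112 to 162 CPM against 54.3 to 1923 CPM). They also overlapped for IDI1 (20.5 to 97.9 CPM against 88.2 to 1184 CPM) and SCD (11.1 to 220 CPM against 107 to 2759 CPM). TOP2A was at 40.5 to 1435 CPM and MKI67 at 25.7 to 193 CPM in the 6 libraries with over 2000 CPM of G2 and M phase transcripts (4 high, 2 low), and at most 0.556 and 0.494 CPM in the other 15. The 1 gene that limma-voom called was ACTB, a cytoskeletal actin gene, which edgeR put at a log2 difference of 0.01 ± 0.18 (SE).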
